A study of Mus musculus with 9 samples.

How the data were processed

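RNA sequencing was carried out on 3 cell populations sorted by flow cytometry from fetal mouse gonads at 12.5 days post coitum, named Sertoli, Leydig and Interstitial in the labels. Per the labels' protocols, the mice carried an Sf1-eGFP transgene, a green fluorescent reporter driven by the gene for the steroidogenic factor SF1 (Nr5a1). Gonads were classed as testes by the presence of testis cords, dissociated with trypsin-EDTA or TrypLE, and stained for CD31 so that germ and endothelial cells could be removed before sequencing. The fluorescence gates that separated the populations are not given in the sources used here. Each sample pooled about 10 sorting experiments made on different days. Per the labels' protocols, a sample A, a sample B and a mix of A and B were prepared per population, with 100 ng of total RNA in each, so that by elimination replicate C was taken as the mix, which the labels do not state. Libraries were made with a stranded, ribosome-depleted total RNA kit, and each was run over 4 lanes.

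The deposited count table gives raw read counts per gene, library and lane; per the submitters' processing notes, the authors aligned reads with TopHat2 2.0.6 to the mouse genome mm10 and counted them with HTSeq. The annotation release and the strand setting of the counting are not given in the sources used here, so a gene and an antisense partner that overlaps it may share reads. The table has 38560 genes and 5 summary lines of HTSeq. The authors also deposited 3 tables of limma results, whose log2 fold changes, average log2 expression, moderated t and log odds scores, and p-values with their adjusted p-values are listed per the file headers. From their values, these tables hold only genes with an adjusted p under 0.05 and a fold change of at least 2. The model and the libraries behind them are not given in the sources used here. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10. It gave 36638 of the gene identifiers a symbol, and the authors' tables gave 34 more.

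Counts were summed over the 4 lanes of each library. The libraries held 33.12 to 39.24 M reads in genes (M, 1e6), and single lanes 8.16 to 9.91 M. Reads outside annotated genes made up 32.23 to 38.52% and ambiguous reads 0.62 to 0.77%. Mitochondrial ribosomal RNA took 13.79 to 18.23% of the reads in genes. A count of 0 in a library allows up to 3 reads, which is 0.0764 to 0.0906 CPM (counts per 1e6 reads in genes). Such floors, and the intervals on ratios of small counts, cover counting error only, because PCR copies are not independent molecules.

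The comparisons used replicates A and B of all 3 populations, 6 libraries with 3 residual degrees of freedom. They were fitted together with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM normalisation, filterByExpr) in R 4.3.3. The filter left 18048 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes within each comparison, and genes were called at an adjusted p of 0.05. Every adjusted p for a single gene comes from edgeR's quasi-likelihood test unless another tool is named. The common biological coefficient of variation was 0.0871 and the prior degrees of freedom were 5.53. With 2 pools per population, each made of many litters, the p-values measure the spread between pools and not between animals. Expression is given as TMM-normalised CPM with the SD over replicates A and B (n = 2), log2 fold changes with their standard errors (SE). A gene was counted as enriched in a population when it was called and at least 2-fold higher there against both others. Beside each such count stand the mean of 20 simulations without any change and the overlap that independent lists of the same sizes would have.

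The fit was tested on simulated counts with known changes in 200 genes per draw, over 5 draws. In Leydig against Sertoli, with 17639 to 17650 genes tested and a dispersion of its own for each gene, it recovered 46% of genes changed 1.5-fold, 67.5% at 2-fold and 89.4% at 4-fold. Of its calls 11.3% were false, and none of the changed genes was called in the wrong direction. In Leydig against Interstitial these shares were 49%, 68.7% and 90%, with 12.8% false calls. When the dispersions followed the trend without scatter, 4.7% and 4.63% of the calls were false. In these simulations the false share therefore exceeded the nominal level where dispersions scattered between genes. That share depends on how many genes change. The comparisons below called 37.5 to 61.8% of genes, so its values do not carry over to them.

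Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and again with an estimated one. With an estimated correlation, camera's test has only the 3 residual degrees of freedom of the fit, so hardly any list could pass. Its adjusted p was 0.554 even for the Sertoli markers in Interstitial against Sertoli, 27 of 27 lower. These adjusted p therefore cannot decide whether correlation between genes accounts for a list result. P-values were adjusted over 72 tests, 24 lists in 3 comparisons, and lists needed at least 5 tested members. Camera asks whether the genes of a list rank higher or lower than the other genes. In simulated counts with the cholesterol biosynthesis list raised 1.5-fold, the test called 2 of the 2 comparisons that held the change and 0 of the 69 tests of other lists. The simulated genes varied independently of each other, so this did not test the preset correlation. The lists covered cell types (fetal Leydig, Sertoli, interstitial progenitor, smooth muscle and pericyte, endothelial, germ, erythroid, macrophage and leukocyte, mesonephric epithelium and coelomic, adrenal cortex, ovarian somatic). They also covered pathways and gene groups (steroidogenesis, cholesterol biosynthesis, cholesterol uptake, storage and transport, hedgehog, Notch, Wnt, TGF-beta with activin and BMP, basement membrane, fibrillar and interstitial matrix, cell cycle, immediate early and heat shock, sex-linked, and disorders of sex development). Lists overlap. Of the 41 genes for disorders of sex development, 29 are in another list, as are 12 of the 16 steroidogenesis genes and 9 of the 15 fetal Leydig markers.

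The comparisons, lists, thresholds and alternatives were chosen before the data were examined, apart from scaling by library size alone. Genes that qualify for naming in each comparison are 18 core genes whatever their result, up to 4 called members per list with the largest change, and the 8 called genes with the largest change in each direction. The latter needed at least 5 CPM in the higher population, no overlap between the 3 libraries of either population, and a symbol that is not a clone or small RNA name. For each enriched set, the 10 genes with the largest smaller fold change qualified under the same conditions. Not every gene that qualified is printed. The alternatives were RLE size factors, a DESeq2 1.42.0 Wald test, limma voom, no low-count filter, a filter at 1 CPM in 2 libraries, all 9 libraries with edgeR and with limma voom, the replicate letter as a block, and each library left out in turn. Further ones were the first 2 lanes alone, the 10 most abundant genes left out, only the 2 populations compared, and other thresholds. Replicate C was kept out of the comparisons because it was taken as a mix, and was used to check that reading. Remaining computations and drawing used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.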

Results

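The data are 9 RNA libraries from fetal mouse testis at 12.5 days post coitum, 3 from each of the sorted populations named Leydig, Sertoli and Interstitial. Leydig cells make androgens, Sertoli cells form the testis cords and secrete anti-Müllerian hormone, and the interstitium is the tissue between the cords. The study's title gives its purpose as the purification of fetal Leydig cells and the search for genes behind disorders of sex development. Reads in genes numbered 33.21 M, 34.22 M and 36.85 M (M, 1e6) in Leydig replicates A, B and C, and 37.32 M, 34.94 M and 39.24 M in Sertoli. In Interstitial they numbered 38.59 M, 33.12 M and 39.21 M.

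Leydig against Sertoli asks what sets the sorted Leydig cells apart from the cells of the cords. The Sertoli libraries were far richer in Sertoli genes. Amh, which encodes anti-Müllerian hormone, was at 1638 ± 62.7 CPM in Sertoli and 442 ± 24.7 in Leydig (SD, n = 2), a 3.71-fold difference. The Leydig libraries were richer in genes of interstitial stroma, such as the growth factor receptor gene Pdgfra (690 ± 44.7 against 227 ± 8.52 CPM) and the signalling gene Wnt5a (291 ± 24.8 against 41.2 ± 6.11 CPM). Several genes of androgen synthesis were not called between the populations with both replicates of each. Cyp17a1, which encodes the enzyme that commits steroids to the androgen route (ENSMUSG00000003555, chromosome 19, 46667165 to 46673172, GRCm38), was at 110 ± 57.2 CPM in Leydig and 74.6 ± 8.86 in Sertoli. All coordinates below are on GRCm38.

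Of Star, Cyp11a1, Cyp17a1, Hsd3b1, Lhcgr and Insl3, none passed the threshold between Leydig and Sertoli. Cyp17a1 differed by 0.56 ± 0.33 on the log2 scale (SE; edgeR adjusted p 0.222). The cholesterol transporter gene Star (0.18 ± 0.19, edgeR adjusted p 0.489), the side-chain cleavage gene Cyp11a1 (0.15 ± 0.37, 0.786) and Hsd3b1 (0.12 ± 0.24, 0.747) were closer to 0. Star was at 57 ± 18.6 CPM in Leydig and 50.2 ± 2.61 in Sertoli, and Hsd3b1 at 113 ± 41.7 and 104 ± 15.5. The luteinising hormone receptor gene Lhcgr (6.79 ± 2.76 and 5.07 ± 1.12 CPM) and the testis descent hormone gene Insl3 (0.707 ± 0.105 and 0.63 ± 0.294 CPM) were low in both. These values rest on single libraries. Without Leydig replicate B, Star (0.53), Cyp17a1 (1.06), Hsd3b1 (0.49) and Lhcgr (0.83) were higher in Leydig with edgeR adjusted p of 0.00358, 0.00205, 0.0485 and 0.0163. Without Leydig replicate A, they were at -0.19, -0.1, -0.32 and -0.07, and Cyp11a1 at -0.52, none of them past the threshold. Cyp17a1 passed it also with no low-count filter (0.6, edgeR adjusted p 0.00028), with the replicate letter as a block (0.468, edgeR adjusted p 0.0365) and with all 9 libraries (0.61, edgeR adjusted p 0.0305). With all 9 libraries, Lhcgr did so as well (0.62, edgeR adjusted p 0.0181). Nr5a1, which encodes SF1 and whose regulatory sequence drives the reporter, was lower in Leydig (199 ± 15.2 CPM) than in Sertoli (397 ± 1.31 CPM).

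All 27 of 27 Sertoli markers were higher in Sertoli than in Leydig, and 27 adjusted over the list alone (median log2 difference -1.8; camera adjusted p 4.19e-15, and adjusted p = 0.554 with an estimated correlation). They included Sox9 (-1.46 ± 0.15), a gene of Sertoli differentiation, Dhh (-1.9 ± 0.08), whose product signals to interstitial cells, and Dmrt1 (-1.62 ± 0.12). Hsd17b3, which makes testosterone from androstenedione, was higher in Sertoli as well (105 ± 10.1 against 28 ± 0.975 CPM). Among the listed steroidogenesis genes, 8 of 16 were higher in Sertoli and 0 in Leydig, with 9 and 0 adjusted over the list alone. Fdxr, which encodes an electron donor of mitochondrial steroid enzymes, fell by 0.99 ± 0.09 on the log2 scale and Nr0b1 by 1.12 ± 0.15. The steroidogenesis list as a whole was lower in Leydig (camera adjusted p 0.0471, and adjusted p = 0.68 with an estimated correlation). The preset result was lost without Leydig replicate B (camera adjusted p 0.309), without Sertoli replicate A (0.0535) and without Sertoli replicate B (0.0532). It was also lost with RLE size factors (0.0513), a filter at 1 CPM (0.0642), all 9 libraries (0.0588 with edgeR, 0.0523 with limma voom) and the replicate letter as a block (0.0999). Genes for disorders of sex development were higher in Sertoli in 19 of 39 tested cases and in Leydig in 4, with 21 and 4 adjusted over the list alone (camera adjusted p 0.00163, and adjusted p = 0.566 with an estimated correlation). Rxfp2, the receptor gene for the Insl3 hormone, was among the latter (4.87 ± 0.252 against 0.526 ± 0.318 CPM).

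Markers of stroma, vessels and leukocytes were higher in Leydig. Erythroid markers were not, with 0 of 13 higher in Leydig and 2 in Sertoli, also adjusted over the list alone (camera adjusted p 0.658). Of 21 interstitial progenitor markers, 19 were higher in Leydig and 0 in Sertoli, the same counts adjusted over the list alone (camera adjusted p 8.77e-11, and adjusted p = 0.554 with an estimated correlation). The orphan receptor gene Nr2f2 (1.82 ± 0.07) and Tcf21 (2.09 ± 0.09) were among them. Endothelial markers were higher in Leydig in 16 of 17 cases, as were 15 of 16 macrophage and leukocyte markers, both the same adjusted over the list alone (camera adjusted p 8.77e-11 and 2.71e-07, and adjusted p = 0.566 with an estimated correlation for each). Sox17 (3.46 ± 0.22) and Cldn5 (3.15 ± 0.18) are examples from endothelium, and C1qb (4.83 ± 0.63) is one from macrophages. Matrix genes followed, with 17 of 25 higher in Leydig and 3 in Sertoli, or 18 and 5 adjusted over the list alone (camera adjusted p 2.41e-05, and adjusted p = 0.566 with an estimated correlation). Decorin (Dcn, 2.78 ± 0.14) and Col1a1 (2.64 ± 0.09) were among them. Of the smooth muscle and pericyte markers, 8 of 12 were higher in Leydig and 1 in Sertoli, also adjusted over the list alone (camera adjusted p 0.00123, and adjusted p = 0.554 with an estimated correlation).

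Of the other lists, 4 were called towards Leydig, while Notch (camera adjusted p 0.0887), TGF-beta, activin and BMP (0.323), cholesterol biosynthesis (0.698) and cholesterol uptake (0.373) were not called. In the hedgehog list 9 of 14 genes were higher in Leydig, among them the target Gli1 (1.27 ± 0.11), and Dhh itself was the 1 higher in Sertoli (camera adjusted p 0.0103, and adjusted p = 0.566 with an estimated correlation). Ptch1, the hedgehog receptor and target, was at 204 ± 8.23 CPM in Leydig and 220 ± 25.8 in Sertoli and was not called (edgeR adjusted p 0.329). Wnt genes were higher in Leydig in 15 of 25 cases and in Sertoli in 5 (camera adjusted p 0.00615, and adjusted p = 0.554 with an estimated correlation). Cell cycle genes were higher in Leydig in 22 of 32 and basement membrane genes in 10 of 19 (camera adjusted p 0.0001 and 0.00711, and adjusted p = 0.566 and adjusted p = 0.608 with an estimated correlation). Adjusted over the list alone, these 4 counts were 9, 15, 23 and 10. Among genes with at least 5 CPM in the higher population and no overlap between the libraries of the populations, those with the largest change towards Leydig were Tm4sf5 (4.38 ± 0.22), Upk1b (4.32 ± 0.28) and the mesothelial gene Upk3b (4.03 ± 0.14). Towards Sertoli they were Fst, which encodes the activin inhibitor follistatin (-2.43 ± 0.39), Irx3 (-2.37 ± 0.25) and Slc9a2 (-2.18 ± 0.18). Their order is not fixed, since over the alternatives Fst ranged from -2.94 to -1.633 and Irx3 from -2.61 to -2.067.

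Fetal Leydig markers were split in this comparison, with 4 of 15 higher in Leydig and 1 in Sertoli, also adjusted over the list alone (camera adjusted p 0.136). The 4 were Dlk1 (1.7 ± 0.11), Vcam1 (1.23 ± 0.14), the corticotropin receptor gene Mc2r (1.05 ± 0.2) and Prlr (0.79 ± 0.19), and the inhibin gene Inha was the 1 higher in Sertoli (-1.27 ± 0.14). In total, edgeR called 6762 of 18048 genes (37.5%), of which 3053 were higher in Leydig and 3709 in Sertoli. The differences were at least 2-fold for 1296 and 1181 of them. Leydig thus held 45.1% of the calls. Scaling by library size alone, chosen after seeing the data, raised the median log2 difference of all genes by 0.102 and that share to 58.8%, so the balance of directions rests on the scaling.

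**Figure D1:**
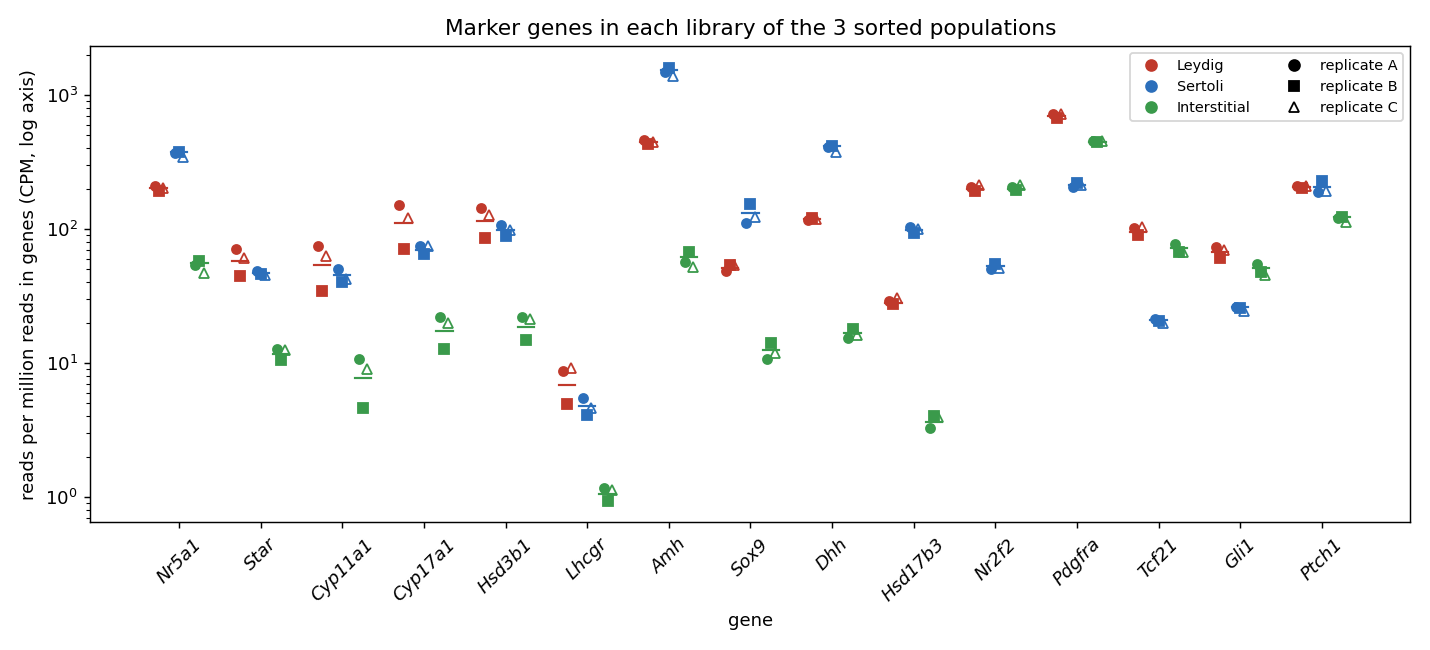
Expression of 15 marker genes in each of the 9 libraries, as plain CPM without TMM factors on a log axis, with bars at the mean of replicates A and B. Star, Cyp11a1, Cyp17a1 and Hsd3b1 overlap between Leydig and Sertoli and lie lower in Interstitial, while Amh, Sox9, Dhh and Hsd17b3 are highest in Sertoli with Leydig in between.

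Leydig against Interstitial asks what distinguishes the Leydig sort from the remaining interstitial cells. Steroid-producing and Sertoli genes were both higher in Leydig, and genes of red blood cells, germ cells and mesonephric tubules were higher in Interstitial. Cyp17a1 was 6.65-fold higher in Leydig, and Star was at 57 ± 18.6 CPM against 11.1 ± 1.39 in Interstitial (SD, n = 2). Over the alternatives, their log2 differences ranged from 2.075 to 3.176 and from 1.988 to 2.651. Amh (442 ± 24.7 against 58.9 ± 7.34 CPM) was 7.51-fold higher in Leydig. The beta globin gene Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) was at 2196 ± 331 CPM in Interstitial and 23.5 ± 15.6 in Leydig.

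Of 15 fetal Leydig markers, 13 were higher in Leydig and 1, Dlk1, in Interstitial, also adjusted over the list alone (camera adjusted p 4.4e-05, and adjusted p = 0.567 with an estimated correlation). Cyp11a1 (2.87 ± 0.42), Lhcgr (2.75 ± 0.33), Hsd3b1 (2.69 ± 0.26) and Star (2.36 ± 0.2) each had both Leydig pools above both Interstitial pools, with edgeR adjusted p from 5.85e-05 to 0.000859. Insl3 was also called (2.13 ± 0.48, edgeR adjusted p 0.00674), but not in the first 2 lanes alone (1.59, edgeR adjusted p 0.0913). In the steroidogenesis list 13 of 16 were higher in Leydig and 1 in Interstitial, also adjusted over the list alone (camera adjusted p 3.66e-05, and adjusted p = 0.566 with an estimated correlation). That 1 was Hsd3b6 (-5.24 ± 0.5), at 22.8 ± 8.16 CPM in Interstitial and 0.598 ± 0.335 in Leydig. Adrenal cortex genes were higher in Leydig in 5 of the 6 tested and in Interstitial in 1, also adjusted over the list alone (camera adjusted p 0.0471, and adjusted p = 0.566 with an estimated correlation). Mc2r (1.3 ± 0.2) and Akr1b7 (2.32 ± 0.31) were among them. The listed Cyp21a1, Cyp11b1 and Cyp11b2 were too low to be tested, with at most 0.295 plain CPM in any library. Against Sertoli, 2 of the 6 were higher in Leydig and 3 in Sertoli, so the call holds against Interstitial alone. The call was lost with RLE size factors (camera adjusted p 0.0522), DESeq2 (0.141), limma voom (0.0648), a filter at 1 CPM (0.0871), all 9 libraries with limma voom (0.0556) and without Interstitial replicate A (0.0651).

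Sertoli markers were higher in Leydig than in Interstitial in 25 of 27 cases, or 26 adjusted over the list alone (median 2.44; camera adjusted p 1.03e-14, and adjusted p = 0.554 with an estimated correlation). The exceptions were Rhox8, not called over all genes, and Dmrt1, which was higher in Interstitial (-0.74 ± 0.12). Cst9 (3.15 ± 0.09), Ptgds (3.05 ± 0.13) and Hsd17b3 (3.02 ± 0.12) were, within the same limits, among the 8 genes with the largest change towards Leydig, behind Cnga1 (3.31 ± 0.26), Acsm3 (3.28 ± 0.18) and Ctrb1 (3.24 ± 0.17). Each of these 6 was also higher in Sertoli than in Leydig. Genes for disorders of sex development followed, with 26 of 39 higher in Leydig and 8 in Interstitial, or 27 and 8 adjusted over the list alone (camera adjusted p 3.11e-05, and adjusted p = 0.554 with an estimated correlation). This list shares 10 of its 41 genes with the Sertoli markers and 6 with the fetal Leydig markers.

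Markers of several other cell types were higher in Interstitial. All but 1 of the 13 erythroid markers were higher there, among them Hbb-bs (-6.54 ± 0.49) and Slc4a1 (-5.81 ± 0.45) (camera adjusted p 6.63e-06, and adjusted p = 0.566 with an estimated correlation). Hbb-bs and Hbb-bt are similar copies, and whether they share reads was not tested. Germ cell markers were higher in Interstitial in 18 of 19 cases, such as Dazl (-2.68 ± 0.53) and Dppa3 (195 ± 19.8 against 29.7 ± 27 CPM), although CD31-positive germ cells were to be removed before sequencing (camera adjusted p 4.5e-06, and adjusted p = 0.566 with an estimated correlation). Over the alternatives, Dazl ranged from -4.13 to -1.973 and the median of the germ cell list from -3.537 to -1.855. Mesonephric and coelomic markers were higher there in 14 of 14 cases, among them Wnt9b (-5.89 ± 0.4) and Cdh16 (-5.1 ± 0.27) (camera adjusted p 2.71e-07, and adjusted p = 0.554 with an estimated correlation). Macrophage and leukocyte markers were higher there in 13 of 16 (camera adjusted p 0.000166, and adjusted p = 0.567 with an estimated correlation). Lyz2 was 1 of these (-2.82 ± 0.55), a call that a DESeq2 test did not make (DESeq2 adjusted p 0.058). Adjusted over the list alone, these 4 counts were 12, 18, 14 and 14.

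Stromal genes went both ways between these populations. Nr2f2 was at 197 ± 9.16 CPM in Leydig and 189 ± 4.51 in Interstitial (edgeR adjusted p 0.495), while Pdgfra (0.7 ± 0.07) and Tcf21 (0.47 ± 0.09) were modestly higher in Leydig. Interstitial progenitor markers split into 7 of 21 higher in Leydig and 6 in Interstitial, also adjusted over the list alone (camera adjusted p 0.672). Endothelial markers were higher in Leydig in 10 of 17 and in Interstitial in 2, or 11 and 3 adjusted over the list alone (camera adjusted p 0.033, and adjusted p = 0.722 with an estimated correlation). The 2 were Plvap (-1.66 ± 0.31) and Pecam1 (-1.22 ± 0.19), the gene for CD31 itself, which was at 69.8 ± 3.43 CPM in Interstitial and 30 ± 8.28 in Leydig. Without Interstitial replicate B the endothelial adjusted p was 0.0861, without Leydig replicate B it was 0.097, with DESeq2 0.251 and with a filter at 1 CPM 0.0699. With the replicate letter as a block, the camera adjusted p of the endothelial list was 0.0519. In the hedgehog list 8 of 14 were higher in Leydig, including Hhip (1.99 ± 0.13) and Ptch1 (0.82 ± 0.08), and Gas1 (-0.75 ± 0.08) was the 1 higher in Interstitial (camera adjusted p 0.0293, and adjusted p = 0.566 with an estimated correlation). The adjusted p of the hedgehog list was 0.0544 without Leydig replicate A, 0.0541 with a filter at 1 CPM and 0.0546 without Interstitial replicate B, where Gli1 (0.45 ± 0.11) was at 0.35 with an edgeR adjusted p of 0.0779. Basement membrane genes were higher in Leydig in 11 of 19, led by Col4a1 (1.38 ± 0.1) and Col4a2 (1.33 ± 0.1). Cell cycle genes were higher in Interstitial in 17 of 32, led by Ccne1 (-0.89 ± 0.14) and Mcm2 (-0.67 ± 0.06). Camera gave an adjusted p of 0.0309 for the basement membrane (adjusted p = 0.645 with an estimated correlation, and 0.0657 with a filter at 1 CPM) and 0.0224 for the cell cycle (adjusted p = 0.608 with an estimated correlation). Adjusted over the list alone, the last 3 counts were 8, 12 and 17.

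Genes linked to the Y chromosome went both ways. Uty (0.6 ± 0.07) and Ddx3y (0.53 ± 0.11) were higher in Leydig, and Zfy1 was higher in Interstitial (-1.89 ± 0.52), a call lost without Interstitial replicate B (-1.8, edgeR adjusted p 0.0652). In the sex-linked list 3 of 7 were higher in Leydig and 2 in Interstitial, or 3 and 4 adjusted over the list alone (camera adjusted p 0.772). In total, edgeR called 8146 of 18048 genes (45.1%), 3966 higher in Leydig and 4180 in Interstitial, of which 1029 and 1726 differed by at least 2-fold. Leydig held 48.7% of the calls, 40.2% with scaling by library size alone and 50.7% with RLE size factors, so this balance rests on the scaling too. Without Interstitial replicate B, the number higher in Leydig fell to 2565.

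**Figure D2:**
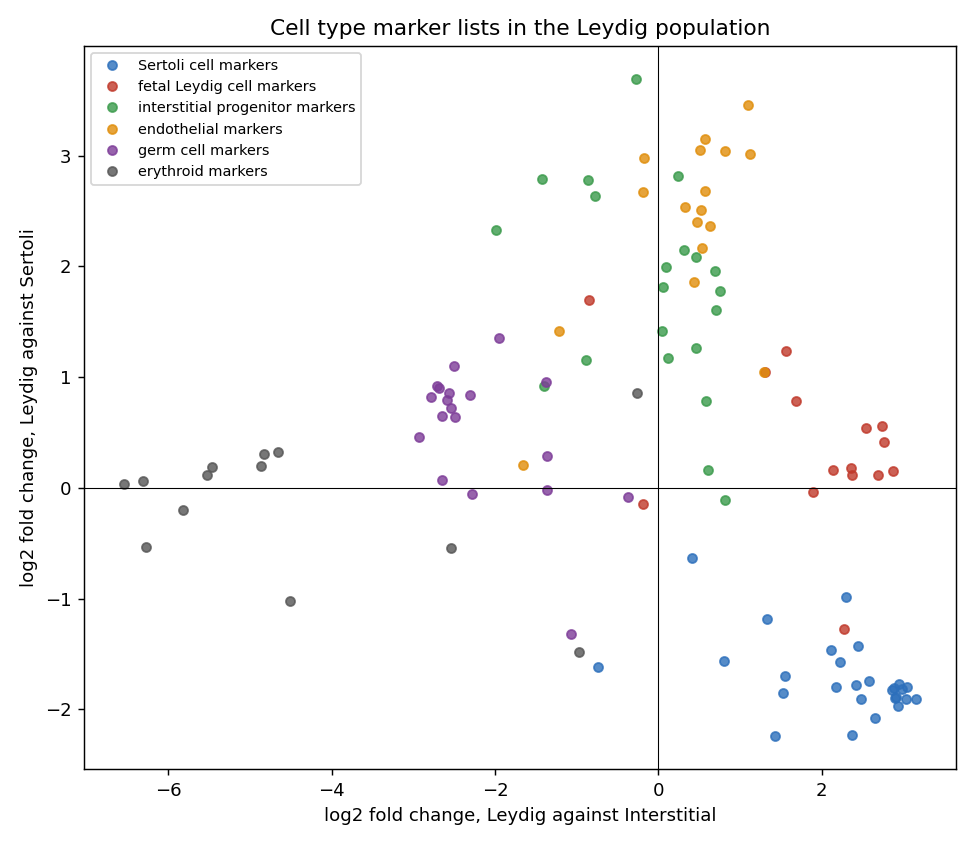
Log2 fold change of Leydig against Sertoli (vertical) and against Interstitial (horizontal) for each tested gene of 6 cell type lists, 1 point per gene, from edgeR on replicates A and B. Sertoli markers lie at the lower right (27 of 27 lower than in Sertoli, 25 of 27 called higher than in Interstitial), and erythroid and germ cell markers lie to the left.

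Interstitial against Sertoli sets the remaining interstitial cells against the cells of the cords and gave the widest differences. Sertoli genes were far lower in Interstitial. Amh was at 58.9 ± 7.34 CPM against 1638 ± 62.7 and Dhh at 15.8 ± 1.96 against 439 ± 1.62 (SD, n = 2). Blood, mesonephric, germ cell and stromal genes were higher in Interstitial, such as Cdh16, a cadherin of tubule epithelium (ENSMUSG00000031881, chromosome 8, 104601911 to 104624396), at 22.3 ± 2.29 CPM against 0.0879 ± 0.0391. Core steroidogenic genes were lower in Interstitial than in Sertoli.

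Sertoli markers were lower in Interstitial in 27 of 27 cases, also adjusted over the list alone (median -4.33; camera adjusted p 4.19e-15, and adjusted p = 0.554 with an estimated correlation). Within the same limits, the largest changes towards Sertoli were those of Ctrb1 (-5.36 ± 0.16), Pnmt (-5.35 ± 0.31), Acsm3 (-5.25 ± 0.17) and Cnga1 (-5.2 ± 0.24). Steroidogenesis genes were lower in Interstitial in 15 of 16 cases, with Hsd3b6 (5.3 ± 0.5) the exception, also adjusted over the list alone (camera adjusted p 3.45e-05, and adjusted p = 0.566 with an estimated correlation). Cyp17a1 (-2.18 ± 0.35), Star (-2.18 ± 0.2), Cyp11a1 (-2.71 ± 0.42) and Hsd3b1 (-2.57 ± 0.26) had both pools apart. Insl3 was called (-1.97 ± 0.49, edgeR adjusted p 0.00681), but not without Sertoli replicate A (-1.4, edgeR adjusted p 0.0674). Fetal Leydig markers were lower in Interstitial in 11 of 15 cases and higher in 1, Dlk1 (2.55 ± 0.11), also adjusted over the list alone (camera adjusted p 0.00367, and adjusted p = 0.638 with an estimated correlation). With a DESeq2 fit that list's adjusted p was 0.0988. Genes for disorders of sex development were lower in 28 of 39 and higher in 8, or 29 and 8 adjusted over the list alone (camera adjusted p 2.5e-05, and adjusted p = 0.554 with an estimated correlation).

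Progenitor markers were higher in Interstitial in 18 of 21, endothelial markers in 16 of 17 and macrophage and leukocyte markers in 16 of 16 (camera adjusted p 4.5e-06, 4.5e-06 and 3.81e-06, and adjusted p = 0.566 with an estimated correlation for each). Lum (4.31 ± 0.3), Kdr (2.87 ± 0.09) and C1qb (6.26 ± 0.56) are examples. Ptprc, the gene of the leukocyte antigen CD45, had 458 reads over both Interstitial libraries and 1 over both Sertoli libraries, a ratio of 461 with a 95% counting interval of 82.4 to 18300. The neutrophil genes S100a9 and Ltf had 0 reads in Sertoli and were at least 360-fold and 170-fold higher in Interstitial, against a floor of 3 reads over both Sertoli libraries. Erythroid markers were higher in 12 of 13, germ cell markers in 17 of 19 and mesonephric and coelomic markers in 14 of 14 (camera adjusted p 0.00109, 0.000664 and 4.55e-06, and adjusted p = 0.567, adjusted p = 0.586 and adjusted p = 0.554 with an estimated correlation). Hbb-bs (6.58 ± 0.49), Dppa3 (3.63 ± 0.57) and Cdh16 (7.92 ± 0.36) stood out in these lists. Adjusted over the list alone, these 6 counts were 18, 16, 16, 12, 17 and 14.

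Matrix genes (18 of 25), Wnt genes (20 of 25) and cell cycle genes (23 of 32) were also mostly higher in Interstitial, or 18, 20 and 24 adjusted over the list alone. Camera gave adjusted p of 0.00123, 0.00279 and 0.000668, and adjusted p = 0.567, adjusted p = 0.554 and adjusted p = 0.566 with an estimated correlation. Within the Wnt list, Rspo3 (4.43 ± 0.35) and Wnt2b (4.26 ± 0.15) were higher in Interstitial, and Wnt6 (-4.18 ± 0.07) and the Wnt target Lgr5 (-4 ± 0.09) were higher in Sertoli. Immediate early and heat shock genes were higher in Interstitial in 3 of 17 and in Sertoli in 5, or 2 and 5 adjusted over the list alone (camera adjusted p 0.401). Nr4a1 (-1.54 ± 0.37) and Btg2 (-1.25 ± 0.37) were lower in Interstitial, calls that were lost without Sertoli replicate B (-1.23 and -0.9, edgeR adjusted p 0.0579 and 0.135). Btg2 was not called either without Interstitial replicate A (-0.81, edgeR adjusted p 0.123) or by DESeq2 (adjusted p 0.0595).

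Several lists were not called by camera in any comparison. Between Interstitial and Sertoli, Notch genes were split into 8 and 7 of 22 (adjusted p 0.698), TGF-beta, activin and BMP genes into 12 and 9 of 28 (0.698) and ovarian somatic genes into 3 and 6 of 9 (0.197). Cholesterol biosynthesis genes were split into 11 and 3 of 22 (0.492), and genes of cholesterol uptake, storage and transport into 6 and 10 of 20 (0.298). Adjusted over the list alone, the TGF-beta split was 12 and 10, and the other 4 were the same. In total, edgeR called 11155 of 18048 genes (61.8%), 5901 higher in Interstitial and 5254 in Sertoli, of which 2879 and 2149 differed by at least 2-fold. Interstitial held 52.9% of the calls. Scaling by library size alone raised the median log2 difference by 0.168 and that share to 65.2%.

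**Figure D3:**
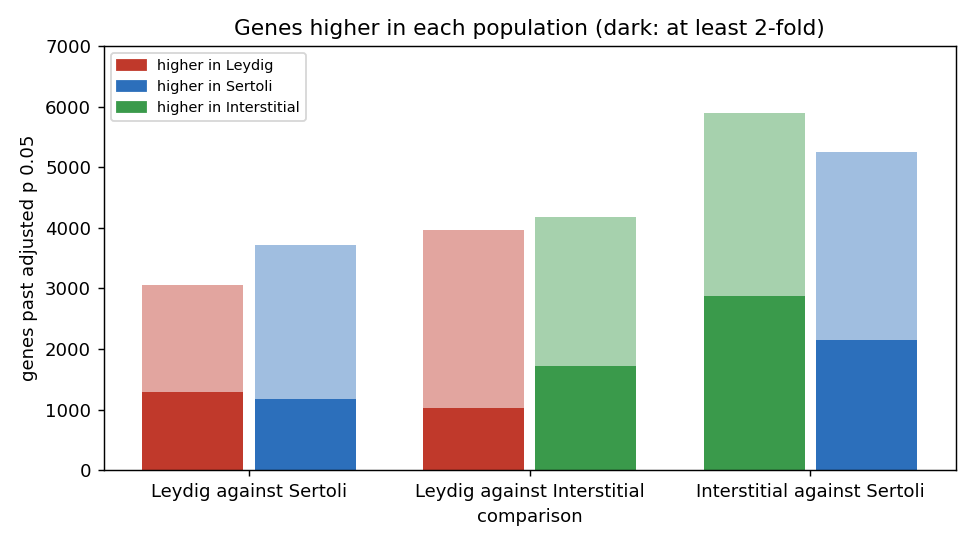
Number of genes past an edgeR adjusted p of 0.05 in each comparison, split by the population in which they were higher, with the genes that differed by at least 2-fold in the dark part of each bar. Interstitial against Sertoli has the most genes, 5901 and 5254, and Leydig against Sertoli the fewest, 3053 and 3709.

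Genes enriched in a single population mark it against both others. In Leydig 56 genes were at least 2-fold higher than in both other populations, in Sertoli 1031 and in Interstitial 1519. The homeobox gene Hoxd10 (ENSMUSG00000050368, chromosome 2, 74691924 to 74695105) was at 32.3 ± 7.28 CPM in Leydig, 8.42 ± 0.711 in Sertoli and 9.12 ± 0.0673 in Interstitial. The neurotrophin receptor gene Ngfr was at 122 ± 26.8 CPM in Leydig, 49.9 ± 2.8 in Sertoli and 50.3 ± 2.9 in Interstitial. The phosphatase gene Ptpro (29.2 ± 5.38 CPM in Leydig), the opioid precursor gene Pdyn (14 ± 3.31), Otof (13.8 ± 2.46), Srpx2 (9.83 ± 0.382) and Btnl9 (5.62 ± 1.01) had the same pattern. Within the limits for naming, Lars2, a mitochondrial leucyl-tRNA synthetase gene, had the largest smaller fold change of the set (90.4 ± 58.9 CPM in Leydig, 23.2 ± 2.97 and 23.8 ± 1.93 in the others). This place is not fixed. Over the alternatives Lars2 fell to log2 differences of 1.071 against Sertoli and 1.043 against Interstitial, and Hoxd10 to no less than 1.691 and 1.578. The plain CPM of Lars2 was 132 in Leydig replicate A, 49.6 in B and 183 in C. A mix of A and B would lie above both only through variation between libraries.

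Simulations without any change gave 0.15, 0.1 and 0.05 such genes on average for Leydig, Sertoli and Interstitial, and independent lists of the same sizes would share 73.9, 141 and 275. The comparisons share their libraries and cannot be split into separate sets of 2 libraries, so part of any excess may come from the shared libraries, and for Leydig there was none over independent lists. Independence is a poor reference for Leydig, because its 2 comparisons can go opposite ways. Of 27 Sertoli markers, 25 were higher in Leydig than in Interstitial and 27 lower than in Sertoli. The 73.9 is therefore no chance level for the Leydig count. The Leydig count rests on single libraries. Without Leydig replicate B it was 98, of which 50 were among the 56, and without Leydig replicate A it was 40, of which 33 were. Of the core genes, Amh, Sox9, Dhh and Hsd17b3 were at least 2-fold higher in Sertoli than in both other populations. Dmrt1 and Nr5a1 were highest in Sertoli as well, but less than 2-fold above Interstitial and Leydig, respectively, and no core steroidogenic gene was in the Leydig set.

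Replicate C behaved differently from an independent sample to a degree that varied by population. Among 10023 genes, its value lay between those of A and B for 54.3% in Leydig, 39.2% in Sertoli and 33.7% in Interstitial, where independent samples would give 33.3%. The variance of C about the midpoint of A and B was 0.122, 0.326 and 0.472 of the variance of A minus B, where independent samples would give 0.75. For a mix, a least-squares fit would place the share of A at 65.9%, 52% and 60.9%. C lay more than 2 times above both A and B for 0 of 9920 genes with at least 10 CPM in Leydig, 0 of 9728 in Sertoli and 0 of 10032 in Interstitial, and more than 2 times below both for 0, 1 and 1. The fitted share takes a mix as given, so it does not test for one. The SD of A minus B was 0.156 to 0.215 on the log2 scale. A difference of 2 times is far beyond that spread, so the counts outside A and B cannot separate a mix from an independent sample. The variance ratio lay on the side of a mix in every population, and the share of genes in between did so in Leydig and Sertoli. That share in Interstitial and Lars2 in Leydig did not. Where A and B differ little, variation between libraries can bring a mix near 33.3% too. The share in Interstitial, where the SD of A minus B was 0.156, therefore does not argue against a mix. Pairs of libraries within a population differed by more than counting noise, with chi-square per degree of freedom from 3.98 for Leydig A and C to 26.1 for Interstitial A and B.

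The authors' deposited limma tables list 1932 genes for Leydig against Sertoli, 1823 for Leydig against Interstitial and 3512 for Interstitial against Sertoli. The edgeR fit called 1898 (98.2%), 1809 (99.2%) and 3506 (99.8%) of them in the same direction, and 0 genes had the opposite sign. Conversely, of the 2477, 2756 and 5031 genes called here with at least a 2-fold difference, 1796, 1729 and 3347 are in the authors' tables. In Leydig against Sertoli, none of Star, Cyp11a1, Cyp17a1, Hsd3b1, Lhcgr and Insl3 is in the authors' table, while Amh is listed there at -1.8 and Pdgfra at 1.66. In Leydig against Interstitial, the authors' table lists Cyp17a1 at 2.63, Star at 2.29 and Amh at 2.96. A total of 45 genes are higher in Leydig in both of the authors' tables, and 34 of these are among the 56 genes enriched in Leydig.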

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

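The test of Y-linked genes was chosen after the Xist values were seen, and the test of the lanes before.

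Xist, the RNA that silences an X chromosome in cells with more than 1, was at 90.8 plain CPM in Interstitial replicate C, a library outside the comparisons. It was at 124 CPM in replicate A and 7.46 in replicate B, which would place the share of A in C at 71.6%. In the Leydig libraries Xist was at 10.7 to 13.4 CPM, and in the Sertoli libraries it was higher, at 16.3 to 27.7 CPM. An error in a single lane is argued against by the lowest value over the 4 lanes of replicate A, 117 CPM. A candidate explanation is XX cells in the pools of replicate A, which would dilute Y-linked transcripts. Ddx3y (75.4 and 89.8 CPM), Kdm5d (55.7 and 60.3), Eif2s3y (84.3 and 90.5) and Uty (48.3 and 49.5) were lower in Interstitial A than in B. These genes were chosen after their values were seen. Set against A and B of the other populations, their mean log2 difference was 0.004 ± 0.048 (SE over 4 genes), with a lower limit at a loss of 6.11% of the Y-linked reads. That limit assumes that a letter means the same in each population and takes 4 genes of the same libraries as replicates. A larger loss is therefore not excluded. A share of XX cells and a change of Xist within XY cells cannot be told apart, because the level of Xist in XX cells of this age was not measured here.

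Reads outside annotated genes, which the comparisons do not use, made up 38.52% in Leydig replicate B, the highest share of the 9 libraries.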

How the results depend on the processing

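Scaling by library size alone was the only alternative chosen after the results were seen. Of the values of the genes examined per comparison under the alternatives, 3422 kept their direction and side of the threshold, 9 lost the call, 10 gained it and 11 changed sign, none of the last called either way. For the list tests that were called, 622 values stayed and 62 lost the call, 38 of them with an estimated correlation, where 0 of the 38 calls were left. With 3 residual degrees of freedom that test could pass hardly any list, so this loss does not measure the correlation. Wnt genes in Interstitial against Sertoli, with an estimated correlation of 0.031, went from a camera adjusted p of 0.00279 to 0.554. Other lists had far higher estimates, such as 0.783 for fetal Leydig, 0.694 for endothelial and 0.649 for macrophage and leukocyte markers. For such lists the preset correlation of 0.01 may be too low and their preset p-values too small, which the few degrees of freedom leave undecided. Of the counts, 178 were within 1.5 times the main value. With all 9 libraries, the genes higher in Leydig than in Sertoli numbered 4714 with edgeR and 4674 with limma voom, in which replicate C is taken as independent. Requiring a 2-fold change left 1296, 1181, 1029, 1726, 2879 and 2149 genes by comparison and direction, in the order of the report. No minimum fold gave 671, 3175 and 3549 enriched genes in Leydig, Sertoli and Interstitial. At an adjusted p of 0.01, 2001 genes were higher in Leydig than in Sertoli, 2586 in Leydig than in Interstitial and 2763 in Interstitial than in Leydig. These follow from the thresholds themselves; the cause of the other changes was not tested. Insl3 in Leydig against Sertoli was at -0.26 in the first 2 lanes, and Nr2f2 in Leydig against Interstitial at -0.007 with library size scaling.

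Leaving out each of the 6 libraries leaves a population with 1, assumed to vary like the others. The counts then ranged from 2063 to 3194 (higher in Leydig) and 2640 to 3160 (higher in Sertoli) in Leydig against Sertoli. In Leydig against Interstitial they ranged from 2565, without Interstitial replicate B, to 3740 (higher in Leydig) and from 2970 to 3951 (higher in Interstitial). In Interstitial against Sertoli they ranged from 4826 to 6672 and from 4104 to 5457. Enriched genes ranged from 40 to 98, 881 to 972 and 1222 to 1636, and called lists from 37 to 41. In Leydig against Sertoli, log2 differences ranged from -0.194 to 0.527 for Star, -0.521 to 0.655 for Cyp11a1, -0.103 to 1.055 for Cyp17a1, -0.32 to 0.494 for Hsd3b1, -0.245 to 0.739 for Insl3, -0.07 to 0.829 for Lhcgr and -0.226 to 0.013 for Ptch1.

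With the replicate letter as a replicate block, each count stayed within 1.5 times its main value, Cyp17a1 in Leydig against Sertoli passed the threshold (0.468, edgeR adjusted p 0.0365) and the steroidogenesis list did not (0.0999), nor did the endothelial list in Leydig against Interstitial (0.0519). The labels do not say that a letter marks a shared day. A minus B correlated over 18048 genes at 0.015 between Leydig and Sertoli, 0.247 between Leydig and Interstitial and 0.099 between Sertoli and Interstitial. These correlations do not exclude a shift shared by a letter in some genes. Immediate early and heat shock genes were higher in B in 16 of 17 in Leydig and 17 of 17 in Sertoli and in Interstitial. Rmrp, picked after its values were seen, was at 1270 and 792 plain CPM in Leydig A and B. It was at 1410 and 683 in Sertoli and 1760 and 874 in Interstitial. Germ cell and endothelial markers did not move the same way in each population. The main comparisons were fitted without the letter. Depth limits genes below about 0.09 CPM.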

Other observations

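The tests of Sertoli and steroidogenic genes below, and the Hox genes, Egr2, Dazl, Gm15564 and the contrasts between pools, were chosen after their values were seen.

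Between Leydig and Interstitial, the direction of Hox genes, which set position along the body, went mostly with the cluster, a pattern that was not tested. Of 18 Hox genes with at least 5 CPM in a population, 17 were higher in Leydig than in Sertoli, and 1, Hoxb9, was lower. All 5 HoxD genes were higher in Leydig than in Interstitial, among them Hoxd9 (72.8 ± 9.88 against 42.4 ± 2.02 CPM; SD, n = 2) and Hoxd10. All 5 HoxA genes, 3 of 4 HoxB genes and 3 of 4 HoxC genes were lower in Leydig than in Interstitial, such as Hoxa5 (2.52 ± 0.513 against 9.18 ± 0.77 CPM). Neighbouring Hox genes overlap in the annotation, so reads may be assigned to either of them, and Hoxc6 alone lay near equality (-0.002). All 14 mesonephric and coelomic markers were lower in Leydig than in Interstitial too (median -2.72).

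The 2 pools of a population differed in several lists. In Leydig, 15 of 15 fetal Leydig markers were lower in replicate B than in A (median log2 difference -0.581), while 17 of 19 germ cell markers and 12 of 13 erythroid markers were higher (1.44 and 1.45). Erythroid markers were also higher in B in 10 of 13 cases in Sertoli (1.22) and 9 of 13 in Interstitial (0.3). The fetal Leydig markers were also lower in B in 15 of 15 cases in Interstitial (-0.24), and 4 of 15 were higher in B in Sertoli (-0.13). Germ cell markers were higher in B in 13 of 19 cases in Interstitial (0.099) and went the other way in Sertoli, with 2 of 19 (-0.39). Dazl was at 22.6 plain CPM in Leydig A and 101 in B. Endothelial markers were higher in B in 16 of 17 cases in Leydig (0.208), 7 of 17 in Sertoli (-0.023) and 1 of 17 in Interstitial (-0.432). For macrophage and leukocyte markers these counts were 16, 10 and 16 of 16 (0.517, 0.055 and 0.41). Sertoli markers moved less, with 12, 15 and 20 of 27 higher in B (-0.004, 0.056 and 0.151). Immediate early and heat shock genes were higher in replicate B in 16 of 17 cases in Leydig and 17 of 17 in Sertoli and in Interstitial, with medians of 0.74, 0.67 and 0.72. Egr2 was at 14 and 43.3 CPM in Leydig A and B, 16.8 and 36.4 in Sertoli, and 11.8 and 30.8 in Interstitial. Gm15564 was at 46.4 CPM in Leydig A, 0 in B and 0.0543 in C, far below what a mix holding much of A would have. This is a single gene, near 0 in every other library, and in Leydig C lay between A and B for 54.3% of genes, the highest share of the 3 populations.

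Sertoli genes were intermediate in the Leydig libraries. A Leydig sort that is nothing but a blend of the other sorts is argued against by the 56 genes at least 2-fold above both, where simulations without change gave at most 1. Sertoli cells, or their RNA, in the Leydig sort at 1 share may be the source, and would place each Sertoli marker at the same fraction of the way from Interstitial to Sertoli. Over the 23 listed markers with at least 5 CPM in Sertoli and 4-fold over Interstitial, that fraction had a median of 26.8% and reached from 18.5% for Fgf9 to 48.2% for Gdnf, with 26% for Amh and 28.3% for Aard, the most abundant and the third most abundant. The 95th percentile was 1.63 times the 5th, which missed the bound set for 1 share (at most 1.5 times). The SD of the log2 fraction was 0.273, which missed the bound for genes expressed by the Leydig-sorted cells each at its own level (SD over 0.5). These therefore cannot be told apart, and the sort gates are not given in the sources used here. Dmrt1, lower in Leydig than in Interstitial (-0.74), is a listed marker that the fold limit left out. For the 56 genes with at least 20 CPM in Sertoli and 16-fold over Interstitial the values were 1.3 and 0.112, within the bound for 1 share. These genes were picked from the data for low values in Interstitial, which leaves out genes that cells in both sorts express, so they do not decide.

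Star, Cyp11a1, Cyp17a1 and Hsd3b1 were higher in Sertoli than in Interstitial and were not called between Leydig and Sertoli. A low share of Leydig cells in Leydig replicate B alone, which bears on the second of these only, cannot be told apart from other reasons for it. Without that library, their median log2 difference between Leydig and Sertoli was 0.591, but Star (0.53), Cyp17a1 (1.06) and Hsd3b1 (0.49) were then called higher in Leydig, from 1 Leydig library. Fetal Leydig cells in the Sertoli sort at 1 share could be a source. The 7 listed markers with at least 5 CPM in Leydig and 4-fold over Interstitial, Inha left out, were at 63.3 to 86.2% of their Leydig plain CPM in Sertoli, the highest 1.36 times the lowest, with Hsd3b1 at 86% and Cyp17a1 at 63.3%. Against Leydig A alone they were at 46.4 to 73.9% (1.59 times) and against Leydig B alone at 86.1 to 132% (1.53 times). Over all 11 listed markers with at least 5 CPM that were called higher in Leydig than in Interstitial, the range was 39.7% (Vcam1) to 95.4% (Ren1), a ratio of 2.4, with Mc2r at 45% and Prlr at 54%. These ratios do not subtract the Interstitial level. In Sertoli, Mc2r (2.78 plain CPM) and Vcam1 (16.1) lay close to Interstitial (2.62 and 14.4), unlike Star (47.1 against 11.7) and Ren1 (63.7 against 18.8). With that level subtracted, these markers would lie further apart. The outcome thus depends on the fold limit, on the Leydig library and on the Interstitial level. For the markers as a set, 1 share and separate sources cannot be told apart, and expression by Sertoli cells themselves was not tested.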
